A study of Mus musculus with 12 samples.

How the data were processed

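The series holds 12 chromatin immunoprecipitation sequencing (ChIP-seq) samples of J1 cells, a mouse embryonic stem cell line. In ChIP-seq, formaldehyde-fixed chromatin is sheared, an antibody pulls down the fragments that carry one protein, and the recovered DNA is sequenced. The labels name an Ino80 ChIP with its input, and a second set of 10 libraries from cells carrying a non-targeting or an Ino80 short hairpin RNA, with antibodies to Oct4, Klf4, Med1 and RNA polymerase II (Pol 2) or input DNA. Each of the 12 groups has 1 sample, so no value below has a replicate error. The labels describe the Nextera XT kit, which cuts and tags DNA with a transposase, for the individual libraries.

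One table was analysed, a list of Ino80 peaks. It was assigned to the Ino80 ChIP because its name carries that sample's title and the series describes the mapping of Ino80. The remaining 11 samples were not analysed here, so the effect of the knockdown on Oct4, Klf4, Med1 and polymerase II was not examined. The submitters' processing notes name CASAVA 1.7, Bowtie 0.12.8, SICER 1.1 and bedtools, and the builds mm9 and hg19, without roles or order. SICER is a caller for broad enrichment that joins neighbouring enriched windows into islands. Its window, gap and false discovery settings, the control library and any pooling are not given in the sources used here.

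As deposited by the authors, the list gives a peak name, chromosome, start, end and a constant strand sign, with no read count, score, fold or p-value per peak. The depth behind each peak is therefore unknown, and no peak could be ranked by strength. Width was used where a ranking was planned. All starts and ends lay on a grid of 200 bp, with starts at multiples of the grid and ends 1 bp short of one. The grid was read as counted from 0 with inclusive ends, so 1 bp was added to both ends of every coordinate printed here. This convention is not stated by the authors. The peak names form an unbroken running number. The peaks were taken as mm9, the mouse build in the submitters' notes, and on chromosome 1 they run past the last gene that the GRCm38 table lists.

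No mm9 sequence, annotation or chromosome lengths were used here. The only gene table was for GRCm38.p6, and apart from that check of the build no coordinate of it was used, and none was converted. For this reason 7 of the planned tests were not run: promoter share, genomic class, occupancy of 19 gene lists, base composition, CpG island promoters, sequence motifs and score by class. The rule fixed for named genes (Ino80, 5 pluripotency genes, list members with and without a promoter peak, and the genes nearest the 10 widest peaks) could not be applied. Regions are named by mm9 coordinates instead. From the GRCm38.p6 table the number of protein-coding genes assigned to each chromosome was taken, and the number whose symbols begin with Olfr, Vmn1r or Vmn2r, the olfactory and vomeronasal receptor families. Genes per Mb divide these GRCm38.p6 gene numbers by the mm9 span of the peaks, so they are comparable between chromosomes only as totals.

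Peaks per chromosome were compared with the share of each chromosome in the summed span from first to last peak. This span replaced the planned chromosome length after the list had been seen. The test was a two-sided exact binomial test with Benjamini-Hochberg adjustment over 20 chromosomes. Because neighbouring peaks are not independent, bins of about 5 Mb were also permuted among the chromosomes 100000 times, two-sided, and 95% intervals of density came from 10000 bootstrap draws of these bins. Crowding was measured as the variance to mean ratio of peak midpoints per 1 Mb bin, with bins counted from each chromosome's first peak. It was compared with 1000 random placements that kept every peak on its chromosome, kept its width and left at least 1000 bp between peaks, the smallest distance in the list. Assembly gaps and unmappable sequence could not be taken out of the spans. Relations across the 19 autosomes were given as Pearson's r and Spearman's rho with two-sided permutation p-values (100000 resamples), adjusted over the 4 relations computed. Chromosome X was kept out of them because its density lay apart from all autosomes. Shares of peaks carry 95% Clopper-Pearson intervals, which cover counting error only.

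The chromosome test was run on simulated lists of 12749 independently placed peaks over the 20 spans. With X set to a density ratio of 0.5 or 0.25, the ratio found was on average 0.504 and 0.252, and the binomial test called X in 20 of 20 lists each. These lists were not crowded and cannot show false calls caused by crowding. Crowded lists were therefore made by drawing every 5 Mb bin from the autosomal bins of the real list. With no difference between chromosomes, the binomial test called X in 60 of 100 such lists and 11.52 of 20 chromosomes on average. The permutation of 5 Mb bins called X in 0 of 100 and any chromosome in 5 of 100. With X thinned to a ratio of 0.25, the permutation called X in 100 of 100. The drawn bins keep no crowding beyond 5 Mb, so crowding on a larger scale was not covered. Alternatives fixed before the data were examined were the widest 50% of peaks, merging of peaks closer than 1000 bp and an expectation from gene numbers. Added after seeing the data were the measure of crowding and its placements, the permutation and bootstrap of 5 Mb bins, the relations across autosomes, the relation of width with crowding, the comparison of X with the autosomes as a group and of its peak widths, the expectation without receptor genes, merging at 5000 bp, other bin sizes and other width classes. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.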

Results

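Ino80 is the ATPase of the INO80 chromatin remodelling complex, and the series set out to map where it sits in the genome of mouse embryonic stem cells. The list analysed came from 1 Ino80 ChIP library of J1 cells, so the values describe that library and no replicate error can be attached to them. It held 12749 peaks on the 19 autosomes and chromosome X, and none on chromosome Y. Whether peaks could be called on Y was not examined, so this does not show that Ino80 is absent there.

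Ino80 occupied broad stretches of chromatin. The median peak was 3600 bp wide, with quartiles at 2400 and 5200 bp, and widths ran from 400 bp to 36.8 kb. Together the peaks covered 55.0 Mb, or 2.16% of the 2553 Mb between the first and last peak of each chromosome. Peaks of at least 10 kb numbered 605, which was 4.75% of the list (95% Clopper-Pearson interval 4.38 to 5.13%), and they held 15.1% of all covered sequence. Only 43 peaks reached 20 kb, 0.337% of the list (interval 0.244 to 0.454%). Width depends on the caller's window and gap settings as well as on the protein.

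The widest peak lay on chromosome 10, from 79596401 to 79633200 in mm9, and spanned 36.8 kb. A peak of 34.8 kb followed on chromosome 4, from 140825601 to 140860400, and one of 32.6 kb on chromosome 5, from 123582001 to 123614600. Peaks of 31.8 kb were found on chromosome 17, from 45727601 to 45759400, and near the start of chromosome 7, from 3191801 to 3223600. The chromosome 5 peak stood alone, with 88.8 kb to its nearest neighbour. The chromosome 10 peak had a neighbour at 1.0 kb, the smallest distance in the list. Gene annotation of these regions was not used here.

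**Figure D1:**
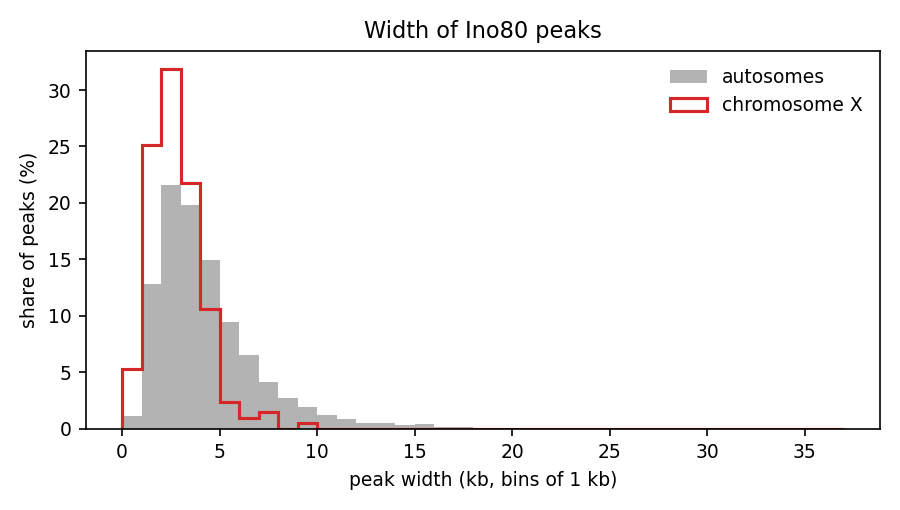
Width of Ino80 peaks in kb (x axis, bins of 1 kb) as the share of peaks in percent (y axis), for the autosomes (grey, 12542 peaks) and chromosome X (red outline, 207 peaks). The median is 3600 bp on the autosomes and 2400 bp on X, where no peak exceeds 9.0 kb.

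Peaks were crowded along the chromosomes, as measured over all chromosomes together. The median distance from one peak to the next was 45.6 kb, against 127 kb on average in random placements of the same peaks on the same chromosomes (range 123 to 130 kb over 1000 placements). The number of peaks per 1 Mb bin had a variance 7.37 times its mean, above the highest placement at 1.52 (one-sided permutation p = 0.000999, the smallest that 1000 placements can give). Of the 1 Mb bins, 20.9% held no peak, compared with 2.43% on average in the placements. The placements used the whole span, including sequence in which peaks cannot be called.

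The densest 1 Mb bin, at 80 to 81 Mb of chromosome 10, held 44 peaks covering 298 kb. Chromosome 7 had 40 peaks at 52 to 53 Mb and 35 peaks at 134 to 135 Mb. Chromosome 4 had 38 at 133 to 134 Mb, chromosome 15 had 36 at 79 to 80 Mb, and chromosomes 11 and 17 had 35 each at 97 to 98 Mb and 35 to 36 Mb. The densest bin of chromosome X, at 7 to 8 Mb, held 17 peaks. At the other extreme, the longest stretches without a peak were all on X. They measured 16.8 Mb (110299401 to 127065400), 13.0 Mb (57432801 to 70473600) and 12.7 Mb (20640001 to 33361800). The longest such stretch on an autosome was 7.64 Mb, on chromosome 7 from 39106201 to 46749200, and 6 of the 10 longest were on X. The longest stretch in any placement, taken over all chromosomes together, was 8.87 Mb. Placements kept the number of peaks of each chromosome, and X had the fewest. That value is therefore no measure of what to expect on an autosome, for which no separate value was computed.

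**Figure D2:**
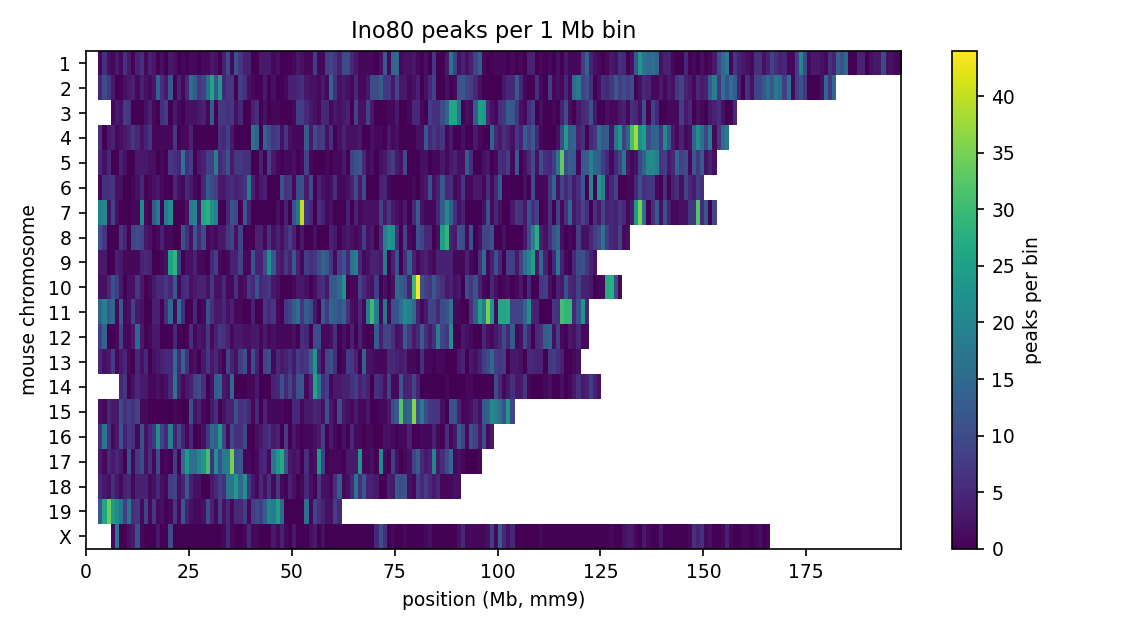
Number of Ino80 peaks per 1 Mb bin (colour) along each chromosome (rows), with bins cut at whole Mb. The x axis gives the position in Mb of mm9, with white beyond the first and last peak. Bright bins mark the crowded regions, such as 80 to 81 Mb of chromosome 10 with 44 peaks, and chromosome X is dark over most of its length.

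Crowded peaks were also the wider ones, a relation that is built in to an unknown degree. Distances ran from edge to edge, so a wider peak reaches nearer to its neighbour. A caller that joins neighbouring enriched windows also makes wider islands where enrichment is dense. Peaks with a neighbour less than 5 kb away (3028 peaks, 23.8% of the list, interval 23.0 to 24.5%) had a median width of 4600 bp (95% bootstrap interval 4400 to 4600 bp). The median was 4000 bp (3800 to 4000 bp) at 5 to 20 kb, and 3400 bp (3400 to 3400 bp) at 20 to 100 kb. For peaks at least 100 kb from any other it was 2600 bp (2600 to 2800 bp). Across peaks, which are not independent replicates, width fell with the distance to the nearest peak (Spearman's rho = -0.31, two-sided permutation p = 0.0001 within chromosomes, the smallest that 10000 permutations can give).

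Chromosome 11 carried the highest density and chromosome X the lowest. Chromosome 11 held 1039 peaks, or 8.78 per Mb (95% bootstrap interval over bins 6.77 to 11.01), which was 1.76 times the number expected from its span. Chromosomes 19 and 17 followed with 7.65 (4.50 to 11.6) and 7.20 (4.65 to 10.1) peaks per Mb. Chromosomes 1 and 14 were the lowest autosomes, both at 3.83 per Mb. The exact binomial test, which treats peaks as independent, called 17 of 20 chromosomes at an adjusted p under 0.05, 9 above and 8 below expectation. It called 11.52 of 20 on average in simulated lists that were crowded but did not differ between chromosomes. A call by this test alone therefore cannot be told from crowding. With the expectation taken from the number of protein-coding genes, 10 chromosomes were called, 6 above and 4 below. Of these, 6 were called in the same direction as by span. Chromosome 11 was among them, but it fell from 1.76 times the expected number by span to 1.095 by gene number. Both expectations share out all peaks with X included, so the low number on X raises the ratio of every autosome. Chromosome 11 had 646 peaks per 1000 protein-coding genes, against 607 over all autosomes. These calls rest on the same binomial test, and the permutation of 5 Mb bins was run by span only. Chromosome 7 went from 1.24 times the expected number by span to 0.770 by gene number, and chromosome 12 from 0.812 to 1.19, both called each time. In the permutation test of 5 Mb bins among chromosomes, which keeps the crowding within bins, 2 chromosomes passed that threshold, chromosome 11 (adjusted p = 0.0005) and X (adjusted p = 0.0002). Chromosomes 17 and 19 were at an adjusted p of 0.12 in that test.

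**Figure D3:**
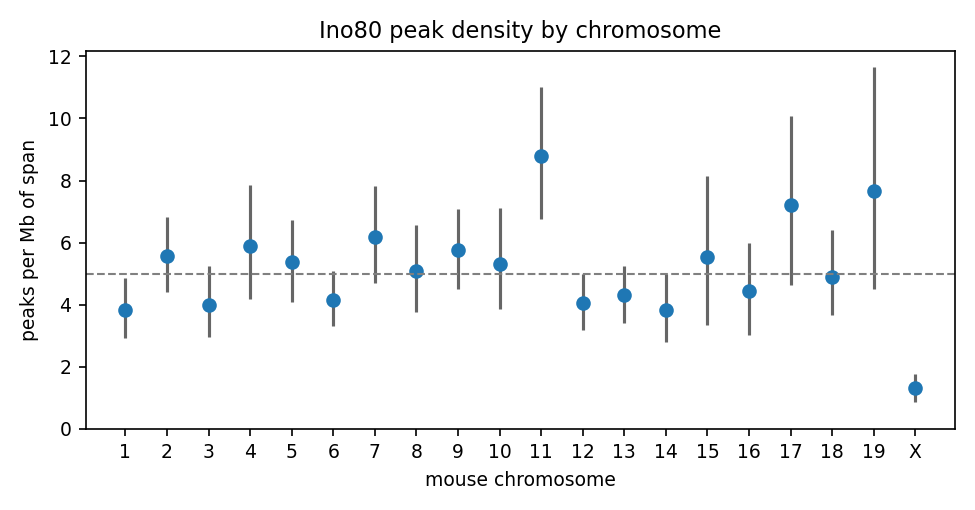
Ino80 peaks per Mb of span (y axis) on each mouse chromosome (x axis). Points are the observed densities, lines their 95% intervals from a bootstrap of 5 Mb bins, and the dashed line the density over all chromosomes. Chromosome 11 lies highest at 8.78 and X lowest at 1.30.

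Chromosome X held 207 peaks, 1.62% of the list (interval 1.41 to 1.86%), on 6.22% of the span. Its density of 1.30 peaks per Mb compared with 5.24 over all autosomes, a ratio of 0.249 (95% bootstrap interval 0.166 to 0.341). The difference passed the two-sided permutation of 32 bins of X against 480 autosomal bins (p = 2e-05), and X lay below the lowest autosome. No peak was found in 59.5% of its 1 Mb bins, compared with 18.4% of autosomal bins. In bins with at least 1 peak, X averaged 3.22 ± 3.38 peaks (SD, 64 bins) and the autosomes 6.41 ± 6.22 (SD, 1946 bins). The peaks of X were narrower, with a median of 2400 bp against 3600 bp (difference -1200 bp). With whole 5 Mb bins as units, 25 on X and 479 on the autosomes, the 95% bootstrap interval was -1400 to -1000 bp (two-sided permutation p = 0.0001, the smallest that 10000 permutations can give). Every autosome had a median of at least 3200 bp. At each distance to the nearest peak the median was lower on X, at 3100 bp against 4600 bp under 5 kb and 2200 bp against 2600 bp at 100 kb or more. None of the 207 peaks on X reached 10 kb, against 4.82% of autosomal peaks (permutation of the same 5 Mb bins, p = 0.0001). All these peaks come from 1 library and 1 chromosome X. The ratio of densities therefore depended on width. It was 0.395 among the narrowest 50% of all peaks, 0.105 among the widest 50% and 0.0332 among the widest 25%.

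The density of Ino80 peaks on the autosomes followed their density of protein-coding genes. Across the 19 autosomes, peaks per Mb correlated with genes per Mb at Pearson's r = 0.88 and Spearman's rho = 0.90 (permutation p = 1e-05 for both, the smallest possible, adjusted p = 2e-05 over 4 relations). Without chromosomes 7 and 11, the most distant in gene density, r was 0.90 (permutation p = 1e-05). With olfactory and vomeronasal receptor genes left out of the gene numbers, r was 0.94 and rho 0.91 (adjusted p = 2e-05 for both), and r was 0.87 without chromosomes 11 and 19. Both densities divide by the same span, so part of the correlation can arise from that shared divisor. The permutation does not address this. Chromosomes are few and differ in many ways, and the correlation says nothing of which genes carried a peak.

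On the autosomes there were 607 peaks per 1000 protein-coding genes. Chromosome 18 had the most, at 841, and chromosome 7 the fewest, at 454. Receptor genes made up 20.5% of the genes of chromosome 7 and 0.196% of those of chromosome 18. With receptor genes left out, chromosome 7 stood at 571 peaks per 1000 genes, and the autosomes ranged from 551 on chromosome 14 to 843 on chromosome 18. Chromosome X had 214 peaks per 1000 genes, below every autosome, although its 6.08 genes per Mb lay above chromosomes 12 and 18, at 5.76 and 5.82. Against an expectation from gene number, X was at 0.364 of the expected peaks.

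**Figure D4:**
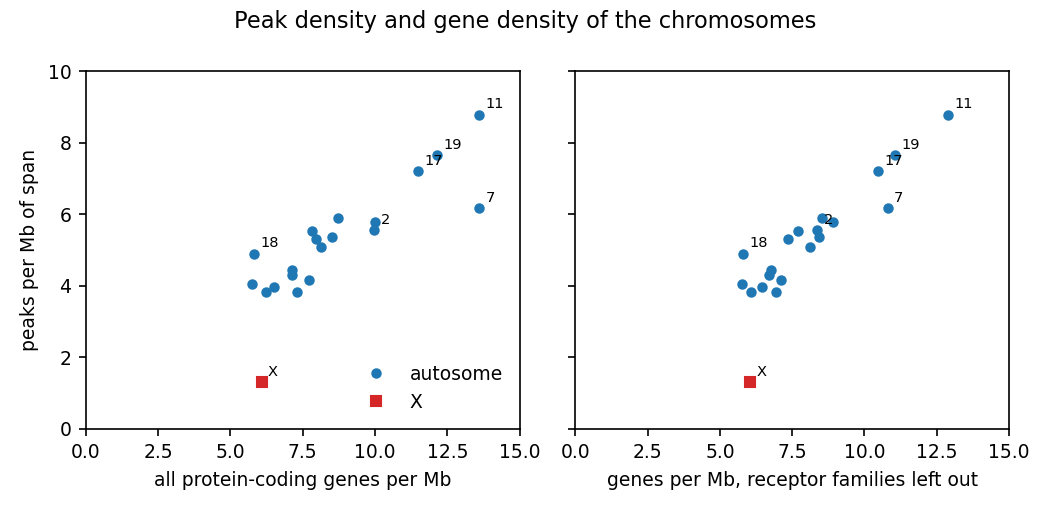
Ino80 peaks per Mb of span (y axis) against protein-coding genes per Mb of span (x axis) for the 19 autosomes (circles) and X (square), with all genes on the left and without olfactory and vomeronasal receptor genes on the right. Chromosome 7 lies to the right of the trend of the other autosomes on the left plot and nearer to it on the right plot, and X lies lowest in both.

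Autosomes with more peaks per Mb also had wider peaks. The median width ran from 3200 bp on chromosome 13 to 4000 bp on chromosome 11, and it correlated with peak density at r = 0.71 (permutation p = 0.00054, adjusted p = 0.00072) and rho = 0.65 (p = 0.00346, adjusted p = 0.00461). Without chromosomes 11 and 19, r was 0.65 (permutation p = 0.005). The medians moved in steps of the 200 bp grid. This relation overlaps with that of width and crowding in the same list, so it is not an independent result.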

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

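The chromosome calls depended on the expectation used. Keeping the widest 50% of peaks left 6374 by construction. Merging at 1000 bp joined no peaks, since none were closer, so it tested nothing. Merging at 5000 bp, chosen after the data were seen, left 11023. The 17 chromosomes that differed from the expectation by span became 15 with the widest 50% and 15 after merging at 5000 bp. With the expectation from gene numbers 10 were called, and 9 with receptor genes left out, of which 6 and 5 were among the 17 with the same direction. Chromosome 7 (1.24 by span) reversed to 0.770 and 0.903, and chromosome 12 (0.812) to 1.19 and 1.11. Chromosomes 10 (1.13 and 1.14) and 18 (1.43 and 1.33) were called by gene numbers only, and 18 stood at 0.980 by span. The permutation of 5 Mb bins called 2. All but this last count rest on a test that treats peaks as independent and called chromosomes in crowded lists without a difference, so they are no measure of how many chromosomes differ. The ratio of X to autosomes stayed below 1 throughout, between 0.0332 (widest 25%) and 0.395 (narrowest 50%), with 0.353 per protein-coding gene. The variance to mean ratio stayed above every placement with bins of 0.2 Mb (2.999) and 5 Mb (17.6), and for the widest 50% (6.20) and narrowest 50% (2.84). The correlation with gene density ranged from 0.84 with X included to 0.94 without receptor genes. The list gives no depth or score per peak, so a stricter threshold could be set on width only, and width on X is itself lower. No paired analysis was possible because each group has 1 sample.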

Other observations

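The comparison of chromosome X with the autosomes as a group, the tests of its empty stretches and of the chromosome ends, the measure of crowding, the merging at 5000 bp and the relations across autosomes were chosen after the list had been seen. All 3 patterns come from 1 library, and the explanations are hypotheses.

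Chromosome X had 0.249 times the autosomal peak density. A lower number of genes does not account for all of it, since X had 214 peaks per 1000 protein-coding genes and the lowest autosome 454. Per protein-coding gene the ratio of X to autosomes was 0.353, nearer to 1 but still below it. Occupied 1 Mb bins of X also held fewer peaks, 3.22 against 6.41 on the autosomes (permutation p = 0.0002), so empty stretches were not the whole difference in this list. That permutation took single 1 Mb bins as units. Neighbouring bins are not independent, so its p-value may be too small. J1 is a male line, so a candidate explanation is that a single X copy yields fewer reads per locus, which would push weak islands below the caller's threshold and narrow strong ones. Before the ratio among the widest 25% of peaks was computed, but after the list had been seen, a ratio closer to 1 was named as a possible sign. The reservation that no value may decide was made at the same time. The ratio there was 0.0332, further from 1. That value decides nothing, since halved coverage also narrows islands, and it restates that the peaks of X are narrower. Lower coverage and weaker binding on X would both narrow its peaks, and without read counts or the input they cannot be told apart.

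Peaks were crowded along the chromosomes. Broad domains cut into neighbouring peaks by the caller may add to this, but after merging peaks less than 5000 bp apart the variance to mean ratio per 1 Mb bin was still 5.41, against at most 1.35 in 100 placements. Differences between whole chromosomes are excluded as the only source, since the placements kept each chromosome's number of peaks and the observed ratio was 7.37 against at most 1.52. Gaps in the assembly and differences in gene density within chromosomes were not tested here and stay open.

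Autosomes differed in peaks per protein-coding gene by more than the counting noise of independent peaks (chi-square = 199, 18 degrees of freedom, p = 1.4e-32). The peaks are crowded, which widens that noise, so whether the autosomes differ beyond crowding stays open. A candidate explanation is that olfactory and vomeronasal receptor genes, which stand in large arrays and are silent in most cell types, lack Ino80 peaks. Across the 19 autosomes, peaks per gene fell with the share of receptor genes (Spearman's rho = -0.61, permutation p = 0.00704, and Pearson's r = -0.69, permutation p = 0.00156). Both measures divide by the same gene number, which includes the receptor genes. A negative relation can therefore arise even if receptor genes are not the ones that lack peaks. The relation rests in part on chromosomes 2 and 7, without which rho was -0.48 (p = 0.0518) and r -0.50 (p = 0.033). It also depends on keeping X apart, since with X included r was -0.29 (p = 0.209) and rho -0.45 (p = 0.0503). Leaving the receptors out lowered the chi-square to 91.9 (p = 6.52e-12), where crowding again widens the noise. Whether receptor genes themselves carry peaks was not examined.

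Chromosome ends were taken as the first and last 10 Mb of the span between the first and last peak, since chromosome lengths were not used. Each end region thus has a peak at its edge, and peak-free sequence beyond it is left out, which can raise its density. The last 10 Mb of the spans held 6.32 ± 3.68 peaks per Mb (SD, 20 chromosomes) and the middle 5.03 ± 1.54. The difference of 1.29 ± 3.18 did not pass a two-sided sign-flip permutation test (adjusted p = 0.173, higher on 12 of 20 chromosomes). The first 10 Mb held 4.77 ± 3.37, a difference of -0.26 ± 3.34 (sign-flip permutation test, adjusted p = 0.777, higher on 7 of 20). Single chromosomes stood out at both ends. The largest excess was in the first 10 Mb of chromosome 19, with 17.2 against 5.75 peaks per Mb in its middle, followed by the last 10 Mb of chromosome 15, with 13.3 against 4.57. The largest deficits were in the first 10 Mb of chromosome 9, with 1.7 against 6.08, and in both the first and the last of chromosome 17, with 3.90 against 8.12 each. Without chromosome 19 the difference of the first 10 Mb was -0.88 ± 1.95 (permutation test, adjusted p = 0.131), and without chromosome 15 that of the last was 0.90 ± 2.73 (permutation test, adjusted p = 0.169).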
